A study of Bos taurus with 4 samples.

How the data were processed

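Bovine morulae (Bos taurus) produced in vitro were compared on the EmbryoGENE bovine 2-colour expression array. Per the labels' protocols, embryos were cultured in synthetic oviductal fluid with either 5 mM glucose (HG) or 0.2 mM glucose (CTL) from day 0 to day 3, then all in control medium to day 5, and were collected 120 h after fertilization. Total RNA of pools of 10 morulae was amplified by T7 transcription in repeated rounds and labelled with Cy3 or Cy5 through a chemical linkage to guanine, per the labels' protocols. Each of 4 arrays carried 1 HG pool and 1 CTL pool. HG was in Cy5 on arrays 1 and 2 and in Cy3 on arrays 3 and 4, per the labels. The arrays were areas of 1 slide, so slide could not act as a batch, and scan dates were not given in the sources used here. No label states that the pools came from separate fertilizations, so p-values of single probes and genes measure the spread between these pools.

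The scanner files held raw spot intensities, the mean and the median of each spot's pixels at 532 nm (Cy3) and 635 nm (Cy5) with the local background, not corrected or normalized, per the file headers. Scanner and quantification program were not given in the sources used here. A second, deposited table held the authors' log2 ratios of the same arrays. The submitters' processing notes name limma without a version. Set against the scanner values, these log2 ratios ran as Cy5 over Cy3 on every array, not turned by dye, with correlations of 0.986, 0.998, 0.996 and 0.997 on arrays 1 to 4. Their slopes lay between 0.950 and 0.966 and their column medians were 0.02, 0.00, 0.00 and -0.01. The exact background correction and normalization behind them stays unknown, and they were used as an alternative.

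Each array had 45220 spots, of which 43794 were probes of transcripts and 1426 were control or corner spots. The mean intensities were background corrected with normexp (offset 50) and normalized within each array by loess, with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Spots marked as ignored in the files (29, 151, 140 and 92 on arrays 1 to 4) were set to missing. At most 2 probes per array and channel reached the scanner ceiling of 65535, and these were kept. A probe counted as above background where its log2 signal exceeded the mean plus 2 SD of 153 negative control spots of the same array and channel. Probes above background in HG on all 4 arrays or in CTL on all 4 arrays were tested, 15740 in all. Between 36.2 and 55.7% of the probes were above background in HG and between 35.4 and 59.2% in CTL. Spike-in control probes, each on several spots of every array, had a median SD of log2 ratio of 0.08 between spots of 1 array. This does not cover differences between arrays, which were larger for these probes. The mean Cy5 over Cy3 ratio of 1 such probe was -0.67 on array 3 against -0.33 to -0.18 on the others. That of another was 1.35 on array 1 against 2.13 to 2.55 on the others. For most of these probes array 3 was lowest. The SD of a gene's log2 ratio over the 4 arrays had a median of 0.51. The number of arrays, 4, limits the precision.

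Gene symbols came from the platform annotation, which gave 1 symbol for 21790 probes, several for none, and left 22004 probes unnamed here. Of 15229 symbols, 14114 were current in the RefSeq gene table of assembly ARS-UCD2.0 and 993 were updated through its synonyms. Each gene was represented by its probe with the highest mean signal among the tested probes, which gave 7377 genes. For 599 of the 1398 genes with several tested probes, the probes differed in direction.

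The log2 ratios were turned to HG over CTL and fitted with limma's lmFit and eBayes against 0, with Benjamini-Hochberg adjustment and a threshold of 0.05. For 36 gene lists, limma's camera with a preset inter-gene correlation of 0.01 was run on the 7315 genes with values on all arrays, with Benjamini-Hochberg adjustment over the 33 lists of at least 5 measured members. Camera compares the statistics of a list's genes with those of the other genes. With a preset correlation, its p-values therefore do not measure the spread between pools. Of 1067 list genes, 942 had a symbol on the array. The lists, the tests, the alternatives except those named as chosen later, and the rule for named genes were fixed before the data were examined. The rule named 12 genes per direction, with the same sign on all 4 arrays. Where too few passed the adjusted threshold, those with the smallest unadjusted p and at least 1.5-fold change filled the places. It also named up to 4 members of each list with the smallest p (up to 8 where the list passed), and a fixed set of glucose, redox, lineage and reference genes where measured. Of the 185 genes it named, the text gives 81, picked for space after their values were seen. Genes named outside this rule are marked as such.

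Alternatives were a dye term, 2 other background treatments, median centring, scale and quantile normalization between arrays, other filters and separate-channel fits with and without the array as replicate block. Others were the authors' log2 ratios, each array left out, other thresholds and variance models, array weights, the mean of a gene's probes, an estimated inter-gene correlation, and fry. Chosen after the data were seen were the median foreground, a covariate made from cumulus cell markers, arrays 2 and 4 alone, and the sign of array 1 or array 3 turned. The fit was tested on simulated data of 7315 genes with normal, independent noise. Its size for each gene was limma's moderated variance, which is drawn toward a common value, so gene variances differed less than in the data. Of 200 genes changed, it recovered 24.3% of those changed 2-fold and 95.0% of those changed 4-fold, with 8.2 false calls per simulation over 20 simulations. A list shifted by -0.25 was found in 100% of them, with 0.1 other lists called per simulation. Simulated genes did not vary together, as real genes do.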

Results

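Transcript levels were measured in bovine morulae that spent the first part of culture in high glucose (HG, 5 mM) or control glucose (CTL, 0.2 mM). Each of 4 arrays set an HG pool of 10 embryos against a CTL pool of 10 embryos, with the dyes exchanged between arrays 1 and 2 and arrays 3 and 4. Median raw probe intensities lay between 210 and 287 in Cy3 and between 153 and 163 in Cy5. Values below are log2 ratios of HG over CTL, as mean ± SD over the 4 arrays (n = 4) unless stated otherwise.

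The comparison asks whether exposure to high glucose during the early cleavage period left a mark on the transcripts of the morula. By camera with a preset correlation, lists of mitochondrial energy metabolism, epithelial junction and trophectoderm genes were lower in the HG pools, while 0 lists passed with an estimated correlation (adjusted p = 0.534 or more for these lists) or with fry. The keratin gene KRT8, an intermediate filament of simple epithelia, had 3.50-fold lower signal in HG (-1.81 ± 0.76), and SLC25A5, an ADP/ATP carrier of the mitochondrial inner membrane, 3.08-fold lower signal (-1.62 ± 0.43); with the sign of array 3 turned they were at -0.89 and -0.52. The claudin genes CLDN6 and CLDN4, which encode tight junction proteins, were at -1.35 ± 0.66 and -1.23 ± 0.65. No single gene passed limma's adjusted threshold (443 of 7377 lay under 0.05 by unadjusted p).

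Of 61 measured genes of oxidative phosphorylation, 52 had lower and 9 higher mean values in HG, and the list median was -0.22. The list was lower in HG by limma's camera test (adjusted p = 0.000353), while the adjusted p was 0.534 with an estimated correlation. Its members with the smallest p were COX4I1 (-0.68 ± 0.32), a subunit of cytochrome c oxidase, ATP5MC1 (-0.58 ± 0.25) and ATP5PF (-0.62 ± 0.39) of ATP synthase, and NDUFA6 (-0.62 ± 0.44) of complex I. Each of these 4 was lower in HG on all 4 arrays. In all, 12 members were lower in HG on all 4 arrays and 0 were higher on all 4, by the recorded dyes. With the sign of array 3 turned, 41 of 61 members had lower mean values and the adjusted p was 0.370 (camera).

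Genes of pyruvate use and the citrate cycle had lower values in HG for 22 of 27 measured members, with a list median of -0.27 (camera, adjusted p = 0.00312). With an estimated correlation the adjusted p was 0.534. Citrate synthase, CS, was at -0.70 ± 0.41, the succinate-CoA ligase subunit SUCLG1 at -0.81 ± 0.47, the succinate dehydrogenase subunit SDHC at -0.66 ± 0.34, and the mitochondrial pyruvate carrier MPC2 at -0.61 ± 0.44. All 4 were lower in HG on every array. Without array 3, the adjusted p of this list was 0.0702 (camera). With array 3 turned it was 0.494, with 18 of 27 members lower.

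Among compaction, junction and polarity genes, 18 of 21 measured members were lower in HG and the list median was -0.37 (camera, adjusted p = 0.00312, and adjusted p = 0.534 with an estimated correlation). CLDN6, CLDN4 and ezrin, EZR (-1.29 ± 0.84), which links the cell membrane to actin, were lower on all 4 arrays. With array 3 turned CLDN6 was at -0.73 and the adjusted p of the list was 0.247 (camera), and with array 1 turned it was 0.0776. CLDN6 and CLDN4 were the 2 members past the threshold when adjusted over the list alone, without adjustment for the number of lists. Over all genes each had an adjusted p of 0.810 (limma).

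The trophectoderm list had 13 of 15 measured members lower in HG, a mean of -0.54 and a median of -0.27 (camera, adjusted p = 0.00312, and adjusted p = 0.748 with an estimated correlation). KRT8 was the 1 member past the threshold when adjusted over the list alone, while over all genes its adjusted p was 0.810 (limma). GATA2, a transcription factor of the trophoblast, was at -1.26 ± 0.81, PLAC8 at -1.14 ± 1.07 and the amino acid transporter SLC7A5 at -0.79 ± 0.64, all lower on 4 of 4 arrays; with array 3 turned these 3 were at -0.30, -0.0400 and -0.31. The keratin KRT18, the partner of KRT8 in filaments, was at -1.39 ± 1.30 and was lower on arrays 2, 3 and 4, with 0.29 on array 1, and was at -0.39 with array 3 turned. In all, 5 of the 15 measured members were lower in HG on all 4 arrays and 0 were higher on all 4, by the recorded dyes. The list medians were -0.67 and -0.97 on arrays 2 and 3, but -0.16 and -0.03 on arrays 1 and 4. Without array 3, the adjusted p of this list was 0.160 (camera). Counts of lower members were not particular to the lists that passed. The reference gene and X-linked gene lists each also had 13 of 15 measured members lower and 2 higher. Their medians were -0.09 and -0.20, and they did not pass (camera, adjusted p = 0.300 and 0.343). The median of all tested genes was -0.04.

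Cell cycle genes had 30 of 41 measured members lower in HG and a median of -0.25 (camera, adjusted p = 0.0154, and adjusted p = 0.748 with an estimated correlation). The checkpoint kinase gene BUB1B was at -0.87 ± 0.33 and the replication licensing gene MCM3 at -0.80 ± 0.50, while BUB1 was at 0.50 ± 0.21, each with the same sign on 4 of 4 arrays. The survivin gene BIRC5 was at -0.61 ± 0.26, with 1 of its 2 probes in this direction. The shift lay mostly on array 3, where the list median was -0.69, against values between -0.10 and -0.05 on the other arrays. Without array 3 the adjusted p was 0.791. With array 3 turned, BUB1B was at -0.24 and MCM3 at -0.16, and 16 of 41 members were lower.

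**Figure D1:**
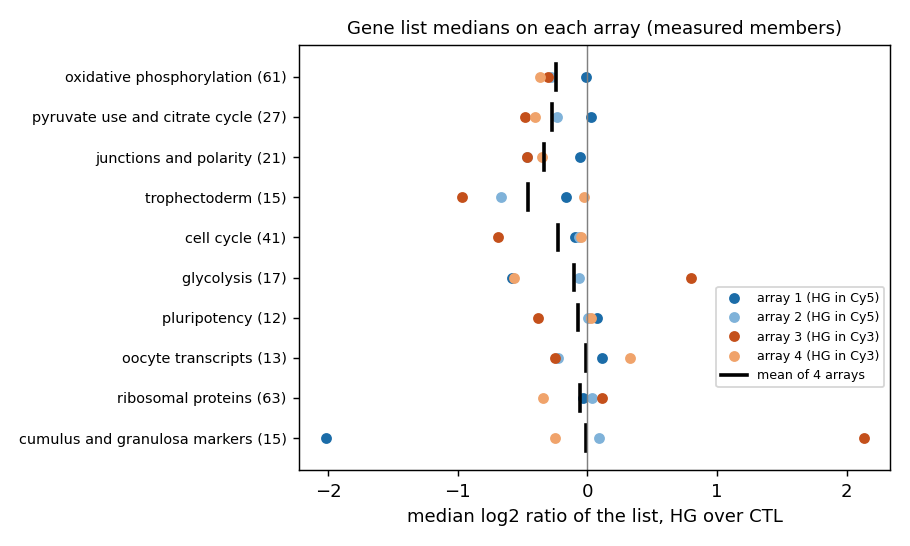
Median log2 ratio of HG over CTL of 10 gene lists on each array (points, coloured by array) with the mean of the 4 array medians (black bar); the number of measured genes stands beside each list. Oxidative phosphorylation, junction, trophectoderm and cell cycle medians lie below 0 on all 4 arrays, but some only just. On array 1 oxidative phosphorylation (-0.01) and junctions (-0.06) lie near the median of all tested probes (-0.04), and trophectoderm lies at -0.03 on array 4. The cumulus and granulosa markers lie at -2.01 on array 1 and 2.13 on array 3.

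The 12 genes named for the smallest p among those lower in HG on every array were SLC25A5, KRT8, LAMTOR3, CD9, LOC613370, PRDX1, CLDN6, SLC7A7, GDPD2, GRHL1, ANXA2 and PARK7. None passed the adjusted threshold (limma, adjusted p = 0.810 for each). With array 3 turned, as its dye record is open, they lay between -1.11 (PRDX1) and -0.20 (GDPD2), with LOC613370 at -0.42. CD9, a tetraspanin of the cell surface, was at -1.05 ± 0.08. LAMTOR3, a scaffold of lysosomal mTORC1 signalling, was at -1.09 ± 0.18 and GRHL1, a transcription factor of epithelia, at -0.96 ± 0.31. The peroxide-reducing enzyme PRDX1 was at -1.39 ± 0.66 and the oxidative stress sensor PARK7 at -0.87 ± 0.23. The membrane-binding annexin ANXA2 was at -1.19 ± 0.57, the cationic amino acid transporter subunit SLC7A7 at -1.09 ± 0.42, GDPD2 at -1.20 ± 0.56 and LOC613370 at -1.06 ± 0.25.

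The 12 genes named by the same rule among those higher in HG also had an adjusted p of 0.810 each, and with array 3 turned lay between 0.24 (C5AR2) and 0.93 (CALB1). CALB1, a calcium-binding protein, was at 1.49 ± 0.68 and was above background in CTL on 3 of 4 arrays. The serine dehydratase gene SDS was at 1.31 ± 0.51 (2.49-fold higher), CPEB4, which regulates cytoplasmic polyadenylation, at 1.26 ± 0.45, and PLAGL1, an imprinted zinc finger gene, at 1.26 ± 0.47. PLAGL1 was the 1 member of the imprinted list past the threshold when adjusted over the list alone. The complement receptor gene C5AR2 was 2.30-fold higher, STEAP1 at 1.05 ± 0.48, MFRP at 1.04 ± 0.46, the elongation factor ELL2 at 1.00 ± 0.37 and the chloride transporter CLCN4 at 0.98 ± 0.46. The glutathione transferase MGST1 was at 0.93 ± 0.34, PLCL2 at 0.85 ± 0.25 and ABHD13 at 0.82 ± 0.24.

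**Figure D2:**
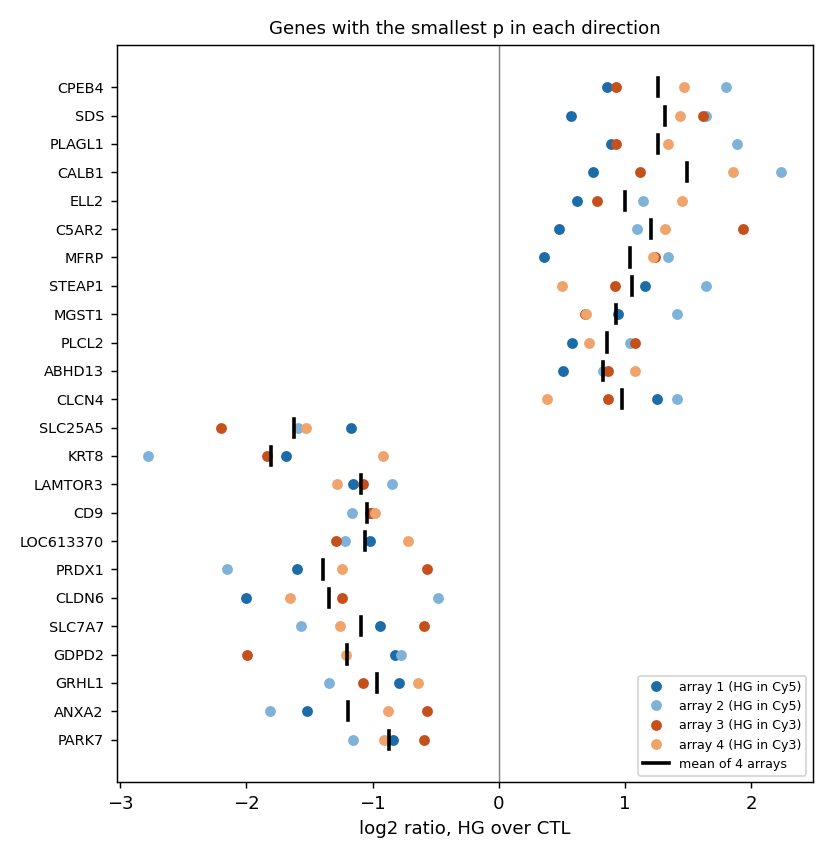
Log2 ratio of HG over CTL on each array (points, coloured by array) and the mean of 4 arrays (black bar) for the 12 genes of each direction with the smallest p and the same sign on every array. All points of the first 12 genes lie above 0 and all points of the last 12 below 0, by the rule that named them; none passed the adjusted threshold.

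The glucose transport list had 4 measured members, too few for a test. Of 17 measured glycolysis genes, 13 had lower and 4 higher mean values in HG, and the list did not pass (camera, adjusted p = 0.498), though with array 3 turned it was lower in HG (adjusted p = 0.0248). The glucose-induced arrestin TXNIP was at 0.61 ± 0.84, with values from -0.06 to 1.74. The lactate dehydrogenase gene LDHA was at -0.42 ± 1.84 and the glucose transporter gene SLC2A1 at -0.52 ± 1.29, each with array 1 below -1 and array 3 above 1. SLC2A3 was at -0.37 ± 0.52 and hexokinase HK2 at 0.50 ± 0.90, and for SLC2A1 and HK2 another probe pointed the other way. PGAM1, a glycolytic mutase, was at -0.36 ± 0.20 and lower on 4 of 4 arrays, LDHB was at -0.40 ± 0.40 and PFKM at 0.43 ± 0.62 (0.13 without array 3). PDK1 was at -0.34 ± 1.38, OGT at -0.23 ± 0.64 and AKR1B1 at -0.23 ± 0.64. PFKP, GFPT1 and HMOX1 did not meet the background criterion, and no probe was annotated to GAPDH. The medians of the glycolysis list, -0.59, -0.07, 0.80 and -0.56 on arrays 1 to 4, moved with the cumulus cell markers of arrays 1 and 3 described below.

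Redox and lineage genes were mixed. In the oxidative stress list 19 of 30 measured members were lower in HG (camera, adjusted p = 0.300, but 0.00895 without array 3, 0.0130 on arrays 2 and 4 alone and 0.000367 with array 3 turned), among them PRDX3 (-0.78 ± 0.46) and the glutathione reductase GSR (-0.68 ± 0.54), both lower on 4 of 4 arrays. The medians of this list, -0.56, -0.24, 0.41 and -0.19 on arrays 1 to 4, had opposite signs on arrays 1 and 3, like the cumulus markers. Thioredoxin, TXN, was at -0.82 ± 0.52. SOD2 was at -0.16 ± 0.47 and CAT at 0.00 ± 0.51. The pluripotency genes POU5F1 and NANOG were at -0.54 ± 0.37 and 0.47 ± 0.65, and their list did not pass (7 of 12 members lower, camera adjusted p = 0.668). With array 3 turned POU5F1 was at -0.02, while NANOG lay between 0.23 and 0.99 under the alternatives. SOX2, CDX2 and GATA3 did not meet the background criterion. The imprinted growth factor receptor IGF2R was at 0.23 ± 0.91 and XIST at -0.22 ± 1.15, and none of the 5 Y-linked genes on the array met it either. The actin gene ACTB was at -0.56 ± 0.33.

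Markers of cumulus and granulosa cells lay far from 0 on arrays 1 and 3, with opposite signs by the recorded dyes. The median of 15 measured markers was -2.01 on array 1, 0.09 on array 2, 2.13 on array 3 and -0.25 on array 4. TIMP1, a protease inhibitor, was at -3.47 on array 1 and 3.15 on array 3. THBS1 was at -5.05 and 4.39, LUM at -5.15 and 3.32, and VIM at -3.97 and 2.13 on the same arrays; these 3 genes were chosen after their values were seen. Not every marker had opposite signs on these arrays. TNFAIP6 was at 0.60 on array 1 and 1.79 on array 3. CYP19A1, the aromatase gene, was lower on 4 of 4 arrays (-0.50 ± 0.25), at -0.83 on array 1 and -0.42 on array 3, with HG above background on 1 of 4. Across 15740 probes, which are not independent replicates, log ratios turned to HG over CTL correlated at -0.46 between arrays 1 and 3 and at 0.26 between arrays 2 and 4. The other 4 pairs lay between 0.04 and 0.14 (Pearson).

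At the level of single features, 0 of 15740 probes and 0 of 7377 genes passed limma's adjusted threshold, with smallest adjusted p of 0.718 and 0.810. By unadjusted p, 443 genes lay under 0.05, 160 higher and 283 lower in HG, where chance alone gives 369, and with median centring in place of loess the split was 81 higher and 383 lower. With array 3 turned it was 296 higher and 592 lower, and with array 1 turned 353 higher and 257 lower. The separate-channel fit likewise called 0 genes. The same sign on all 4 arrays was seen for 428 genes higher and 651 genes lower in HG, 14.6% of genes, where chance gives 12.5%, and with array 3 turned for 611 and 724 genes (18.1%). At least 1.5-fold change was seen for 124 higher and 217 lower of these genes, and for 203 and 381 with array 3 turned. With a dye term in the fit, 0 probes showed a dye effect past the adjusted threshold. By unadjusted p, 917 of 15740 probes lay under 0.05 for this term, where chance alone gives a share of about 0.05.

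With the sign of array 3 turned 0 of the 5 lists passed, with adjusted p between 0.167 and 0.744, and without array 3 2 passed, oxidative phosphorylation and junctions (adjusted p = 0.0185 each). Arrays 2 and 4 alone, chosen after the cumulus markers were seen, kept 4 of the 5 lists past the threshold and lost cell cycle (adjusted p = 0.485). With array 3 turned, members lower in HG numbered 41 of 61 for oxidative phosphorylation, 18 of 27 for citrate cycle, 13 of 21 for junctions, 9 of 15 for trophectoderm and 16 of 41 for cell cycle. Without array 3, on arrays 2 and 4 alone and with array 3 turned, oxidative stress and cholesterol synthesis also passed as lower and embryonic genome activation as higher (adjusted p = 0.0185, 0.00416 and 0.00180 for the last). Primitive endoderm passed as lower without array 3 (adjusted p = 0.0422) and with array 3 turned (adjusted p = 0.00545). Its medians, -1.25, -0.40, 1.12 and -0.48 on arrays 1 to 4, were displaced in opposite directions on arrays 1 and 3, like the cumulus markers. The medians of oxidative stress (-0.56 and 0.41) and cholesterol synthesis (-0.43 and 0.22) also changed sign between these arrays. The cumulus list itself passed as lower without array 3 and with array 3 turned (camera, adjusted p = 0.0185 and 0.000367).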

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

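The tests of dye record, treatment and dye bias for the cumulus pattern, of other cells and dye bias for the lists, and of the sign patterns for the gene count were chosen after the results were seen. The bound for the dye record shares was first 50% and was widened to 60% after the share of array 3 was seen, because genes move together and the interval is too narrow. Of 125 results tested for 1 array far from the other 3, 8 stood out, and chance gives about 1 in 20.

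Cumulus and stromal marker genes were strongly displaced on arrays 1 and 3, in opposite directions by the recorded dyes. Whatever the record of array 3, an effect of high glucose would displace the marker medians of arrays 2 and 4 too, where the larger distance from 0 was 0.25, and a dye bias would need medians near -2 in Cy5 over Cy3 there, where the lower value was 0.0913. Of 433 genes past 1.5-fold the same way on arrays 2 and 4, 71.6% had the same sign on array 1 (exact binomial interval 67.1 to 75.8%). By the bound alone this would argue against a wrong dye record of array 1. For array 3 the share was 55.2% (50.4 to 59.9%), which would argue against a wrong record by the first bound of 50% but leaves it open by the widened one. However, some stromal genes lay below 0 on arrays 1, 2 and 4 and above 0 on array 3. RNA of other cells could thus raise the share of array 1 and lower that of array 3, so neither share separates the dye record from such RNA. A candidate explanation is RNA of other cells in the CTL pool of array 1 and, by the recorded dyes, the HG pool of array 3: in a second list of stromal genes written before its values were seen, 9 of 16 measured members (56.2%, exact interval 29.9 to 80.2%) lay below -1 on array 1 and above 1 on array 3, against 5.33% of all genes. VIM and LUM, among the most abundant markers (mean log2 signals of 13.09 and 11.98), moved this way, but morulae may express some of these genes themselves.

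The lower values of the 5 lists in HG could stem from unequal numbers of such cells, from gene-specific dye bias or from a signal-dependent bias. For oxidative phosphorylation, citrate cycle, junctions and trophectoderm, such cells as the whole cause would need medians at least as far from 0 on array 1, with its far displaced markers, as on array 2. These were up to 0.162 from 0 on array 1 against 0.23 to 0.67 on array 2, with each difference past its spread. That spread treats genes as independent, and the citrate cycle difference of 0.20 barely passed it (0.19). The comparison does not test such cells as a part of the cause. All 4 medians were lower on array 3 (-0.97 to -0.30) than on array 1 (-0.16 to 0.03), so a part played by such cells stays open. A dye bias of equal size on every array cancels in the main fit, since HG was in Cy5 on arrays 1 and 2 and in Cy3 on arrays 3 and 4. The 4 lists also stayed past the threshold on arrays 2 and 4, with HG in opposite dyes (highest adjusted p 0.00281, camera). That pair is part of the same data and was chosen after they were seen. The cell cycle shift lay on array 3, where such cells would need an opposite shift on array 1 (median -0.10) and a dye bias a like shift in Cy5 over Cy3 on the other arrays (highest median 0.0491, against 0.69 on array 3). Among random lists matched on mean signal, 0 of the 5 lists had a median inside the central 95%. The 5 lists were picked as lower in these same data, and randomly drawn genes do not move together. Loess had also removed the trend with signal within each array, and the random lists had typical medians of -0.07 to -0.04. This shows only that genes of like signal were not shifted as far, and does not exclude a signal-dependent bias. The dye record of array 3 stays open, and that of array 1 is not settled by its share of genes. List genes that move together by chance stay open too, since 0 lists passed with an estimated correlation. So does an effect of high glucose on the embryos, which is a hypothesis. A difference in embryo stage between pools was not settled for the trophectoderm list, as described below. For the other lists it was not tested.

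The 4 arrays allow 8 sign patterns, too few for a share under 0.05. The real pattern gave 443 genes at unadjusted p under 0.05, and 4 of the 8 patterns gave as many, the highest other being 888, with array 3 turned. The real pattern gave 5 lists and the highest other 6, and 4 patterns gave at least as many. A wrong dye record of array 3 and RNA of other cells on arrays 1 and 3 would both give more genes with array 3 turned, and no test separated them.

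MFRP stood at 0.36 on array 1, below 1.22 to 1.34 on the others. EZR was at -2.54 on array 2, where the others lay between -0.91 and -0.84. GSR was at -1.49 on array 2, with the others between -0.44 and -0.35. PDK1 was at -2.41 on array 1, with 0.20 to 0.48 elsewhere. The cell cycle list median was -0.69 on array 3, with the others between -0.10 and -0.05. The pluripotency list median was -0.38 on array 3, with 0.01 to 0.07 on the others. The reference gene list median was -0.27 on array 4, with -0.07 to -0.05 on the others. Array 3 had the highest median raw Cy3 intensity, 287, against 210 to 212.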

How the results depend on the processing

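The median foreground, the cumulus covariate, arrays 2 and 4 alone and the turned signs of array 1 or array 3 were chosen after the data were seen, and the cause of the changes below was not tested unless stated. The count of changed genes and of changed probes stayed at 0 under all other alternatives but those named here. At unadjusted p with 1.5-fold change, a looser threshold, 364 genes and 800 probes passed. On arrays 2 and 4 alone 134 genes and 78 probes passed, in a fit with 1 residual degree of freedom that gave every gene the same prior variance. Genes at unadjusted p under 0.05 numbered 443, against 828 with no filter, where more genes were tested, 736 with array weights, 953 with the cumulus covariate, 885 on arrays 2 and 4 alone, 888 with array 3 turned, and 181 to 731 with each array left out (587 without array 1, 181 without array 2, 731 without array 3 and 196 without array 4). Median centring moved the median of all genes from -0.04 to -0.11 and the share of lower genes among those at unadjusted p under 0.05 from 63.9% to 82.5%.

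All 5 lists kept their direction and passed under each dye, background, between-array, filter, separate-channel (with and without the replicate block), deposited-ratio and probe-mean alternative, under median centring and with the cumulus covariate; the dye term and the covariate are close to orthogonal to treatment, so they could hardly move the estimates. With an estimated correlation 0 lists passed, with adjusted p of 0.534 for oxidative phosphorylation, citrate cycle and junctions and 0.748 for trophectoderm and cell cycle. With fry 0 lists passed, with adjusted p of 0.398 for oxidative phosphorylation and citrate cycle, 0.269 for junctions, 0.630 for trophectoderm and 0.682 for cell cycle; fry's mixed adjusted p were 0.350, 0.705, 0.395, 0.374 and 0.301 in the order oxidative phosphorylation, citrate cycle, junctions, trophectoderm, cell cycle. With array 3 turned camera's adjusted p were 0.370, 0.494, 0.247, 0.744 and 0.167 in the same order. Camera then placed the last 2 lists higher in HG relative to the other genes. For trophectoderm 9 of 15 members still had lower values (median -0.04), while the cell cycle median was 0.10. With array 1 turned, junctions had an adjusted p of 0.0776. Cell cycle had 0.0576 with the median foreground and 0.485 on arrays 2 and 4 alone. With each array left out the ranges were 0.000382 to 0.0702 for citrate cycle, 8.14e-05 to 0.160 for trophectoderm and 0.00246 to 0.791 for cell cycle, each highest without array 3. Lists higher in HG numbered 0, with 0 to 1 when an array was left out and 1 each on arrays 2 and 4 alone, with array 3 turned and with array 1 turned.

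Of 84 genes named in the text, 65 kept their direction under all alternatives run. Many were named for the same sign on all 4 arrays, so leaving arrays out could not reverse these. Most other alternatives reprocessed the same arrays, so the count says little about how reproducible the directions are. With array 3 turned, 35 of the 84 genes fell under 0.5 of their log2 ratio or changed sign, and without array 3, 5 did. With array 1 turned the log2 ratio was 0.10 for AKR1B1, 0.13 for SLC2A3, 0.15 for HSP90AB1, 0.21 for SLC2A1, -0.27 for HK2, 0.68 for XIST, 0.86 for PDK1, 0.93 for LDHA, 1.24 for TIMP1, 1.62 for VIM, 2.14 for THBS1 and 2.24 for LUM. With array 3 turned it was -0.23 for PFKM, -0.26 for TXNIP, -0.29 for TNFAIP6, 0.12 for CAT and 0.16 for OGT. On arrays 2 and 4 alone it was 0.0514 for SLC2A3, 0.0725 for XIST, 0.15 for OGT, 0.19 for VIM, 0.25 for LUM and 0.42 for PDK1. CAT was at 0.07 with quantile normalization and with the deposited ratios (0.0721 and 0.0651). With each array left out the ranges were -1.16 to 0.34 for LDHA, -0.62 to 0.34 for PDK1, -0.35 to 0.0320 for SOD2, -0.24 to 0.15 for CAT, -0.0498 to 0.60 for IGF2R, -0.55 to 0.31 for XIST, -1.71 to 0.50 for TIMP1, -1.98 to 1.17 for THBS1, -1.55 to 1.28 for LUM and -1.19 to 0.84 for VIM. Genes that did not meet the background criterion, among them CDX2 and SOX2, were not tested.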

Other observations

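Tests of the lists below were planned, except that arrays 2 and 4 alone, the turned signs and the test of embryo stage were chosen after the values were seen. The genes were named by the rule fixed before the data were examined. The lists of lipid synthesis and protein folding did not pass in the main fit, and the genes given are among their members with the smallest p. ATP-citrate lyase, ACLY, which makes acetyl-CoA for lipid synthesis, was at -0.97 ± 0.50 (SD, n = 4), and the sterol synthesis genes FDFT1 and SQLE were at -0.79 ± 0.54 and -0.57 ± 0.34. In the cholesterol synthesis list 12 of 17 members were lower (camera, adjusted p = 0.234, but 0.0185 without array 3, 0.0302 on arrays 2 and 4 alone and 0.0112 with array 3 turned), in the fatty acid and lipid storage list 14 of 21 (adjusted p = 0.286), and in the fatty acid oxidation list 11 of 16 (adjusted p = 0.360). The cholesterol synthesis medians, -0.43, -0.43, 0.22 and -0.28 on arrays 1 to 4, had opposite signs on arrays 1 and 3, like the cumulus markers. The chaperone genes STIP1 (-1.13 ± 0.77), HSP90AB1 (-0.80 ± 0.79) and HSPE1 (-0.58 ± 0.31) were lower on 4 of 4 arrays, with 10 of 14 heat shock genes lower (adjusted p = 0.234). Calnexin, CANX, was at -0.94 ± 0.48, and 14 of 21 unfolded protein response genes were lower (adjusted p = 0.483, but 0.0440 on arrays 2 and 4 alone).

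The genome activation gene ZSCAN4 was at 0.71 ± 0.51 and the endoderm factor FOXA2 at 1.03 ± 0.54, each above background in CTL on 3 of 4 arrays, while fibronectin, FN1, was at -0.72 ± 0.30. The BMP target ID2 was at 0.96 ± 0.48 and higher on 4 of 4 arrays. In amino acid and 1-carbon metabolism, AHCY and SMS were at -0.81 ± 0.37 and -0.89 ± 0.53, while GOT2 was at 0.71 ± 0.44. The hypoxia target BNIP3 was at 0.41 ± 0.16. Ribosomal protein genes had 39 of 63 members lower and a median of -0.04 (camera, adjusted p = 0.850). The cumulus markers, including TNFAIP6 (0.60 ± 0.90), did not pass as a list (adjusted p = 0.889), but the list was lower in HG without array 3 (adjusted p = 0.0185) or with array 3 turned (adjusted p = 0.000367) and higher without array 1 (adjusted p = 0.0156) or with array 1 turned (adjusted p = 0.000502). For 5 lists, none past the threshold, the median or the mean differed in sign from the test.

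A lower trophectoderm list could come from HG pools with fewer advanced embryos, which would leave more oocyte transcripts. In the oocyte list 9 of 13 members were higher (camera, adjusted p = 0.498). On arrays 2 and 3, where the trophectoderm medians were lowest (-0.67 and -0.97), the oocyte medians were -0.23 and -0.25, opposite to what this needs, but the spread of the median was 0.14 on array 2 and 0.27 on array 3. On so few members the stage of the pools cannot be told apart from an effect on the trophectoderm genes themselves.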
